A study of Boehmeria nivea with 6 samples.

How the data were processed

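RNA was sequenced from leaf, root and stem of 30-day-old ramie plants of the wild accession QYZM and the cultivar ZSZ1, with 1 library for each tissue of each variety. Per the labels' protocols, total RNA of each of the 6 samples was extracted and made into its own cDNA library. The authors deposited FPKM values for 20693 genes in 1 table with a column for each library. The submitters' processing notes name Bowtie2 and RSEM, without versions or roles. The values carry up to 6 significant digits, and which program wrote them is not known, so neither is what a listed 0 stands for. The genome assembly, gene models and strand handling behind the values are not given in the sources used here. The table pairs its identifiers with no gene names, products or coordinates, and no genome or annotation was used here, so genes are given by identifier and their functions are not described. Of the identifiers, 20158 carry 1 of 14 numbered prefixes and 535 the prefix Un. Reads shared between near-identical genes could have been split or misassigned in the authors' counting, which FPKM values alone do not show.

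FPKM are relative values: a gene that takes a larger share of a library lowers all others. Column totals ranged from 306497 in ZSZ1 leaf to 433435 in QYZM leaf. Read counts per library were not known, so no counting interval or detection limit is given, and an exact 0 is reported as listed at 0. Relative depth was estimated from genes below 0.2 FPKM in a pair of libraries, where log2 ratios cluster at the ratio of 1 fragment in each, if whole fragments were counted. The 15 peaks were combined by least squares, with a largest residual of 0.07 on the log2 scale. The peaks stood 3.1 to 14.7 times above the median density and were weakest for the leaf libraries.

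Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with tissue and variety terms, moderated variances with a mean-variance trend) on log2(FPKM + 1) of the values as deposited. The 14941 genes with at least 1 FPKM in at least 2 of the 6 libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold on the log2(FPKM + 1) scale. Counts at an unadjusted p below 0.05 are also given, a bound that a share of 0.05 of tested genes would pass with no difference. With 1 library per tissue and variety, the error term is the departure of the libraries from additivity, on 2 residual degrees of freedom moderated by 3.71 prior degrees of freedom. It holds tissue-by-variety differences as well as noise between libraries. A difference that exists in 1 variety alone therefore cannot be tested. The labels name no batch, and p-values measure the spread among these 6 libraries, since nothing says how many plants each came from. Descriptive values (correlations across genes, tissue-enriched genes, genes at least 4-fold apart) were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

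The fit was tested on simulated data of the same 14941 genes, with 100 genes changed 4-fold and 100 changed 16-fold. With variances drawn from the fitted prior, it recovered 31 of the 4-fold and 94 of the 16-fold changes for leaf against root, 14 and 92 for stem against root, 15 and 93 for leaf against stem, and 57 and 97 for ZSZ1 against QYZM. False calls were 3.8% to 6.0% of all calls. With each gene's own moderated variance, 78 to 93 of the 4-fold and 99 to 100 of the 16-fold changes were recovered and false calls were 5.9% to 11.5%. In the data, 5252 and 4397 genes were called in the leaf comparisons and 802 for stem against root, a larger share than was changed here. Adjusted p-values depend on that share, so these rates do not carry over to the tissue comparisons. The simulation also gave all libraries of a gene the same variance and held no tissue-by-variety differences.

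The design, the alternatives and the rule for named genes were fixed before the data were examined. Because the identifiers could not be paired with names, the rule gave for each comparison the 2 called genes with the largest positive and the 2 with the largest negative log2 difference among those with the same sign in every variety or tissue. The planned tests of gene lists (photosynthesis, cell wall, lignin, transport and others) needed names and were not run. Alternatives were pseudocounts of 0.1 and 5, no filter on low values or a mean of at least 5 FPKM, scaling to a total of 1000000, median-of-ratios scaling, quantile normalization, no trend or robust moderation, other fold thresholds, no blocking term, and leaving out each library. Scaling with the 100 highest genes of any library (287 in all) left out of the total, and following the percent of called genes that were higher, were added after seeing the data.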

Results

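Gene expression was profiled by RNA sequencing in ramie (Boehmeria nivea), a perennial bast-fibre crop, from leaf, root and stem of 30-day-old plants of a wild tenacissima accession (QYZM) and a cultivar (ZSZ1). One library was made for each tissue of each variety, 6 in all, so no tissue of a variety had a replicate. The table gave FPKM (fragments counted on a gene, scaled by gene length and library size) for 20693 genes by identifier alone. The number of reads per library was not known. If whole fragments were counted, the steps between the lowest values placed the 6 libraries at 0.91 to 1.14 times their common mean depth.

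A total of 10930 genes reached 1 FPKM in all 6 libraries, and 4810 did so in none. QYZM had 13485 detected genes (at least 1 FPKM) in leaf, 14079 in root and 13953 in stem. ZSZ1 had 12536 in leaf, 13317 in root and 13622 in stem. Expression was more concentrated in leaf than in the other organs of both varieties. The 100 highest genes held 31.6% of the summed FPKM in QYZM leaf and 31.0% in ZSZ1 leaf, against 17.1% to 19.9% in the root and stem libraries. The highest gene was the same in both leaf libraries and reached 13029 FPKM in QYZM and 14100 FPKM in ZSZ1, or 3.01% and 4.6% of the library totals. In both stem libraries the highest gene was Bnt02G002335, at 4742 and 6513 FPKM.

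Libraries of one tissue from the 2 varieties resembled each other more than they resembled any other tissue. Across 14941 tested genes, the Pearson correlation of log2(FPKM + 1) between varieties was 0.918 for leaf, 0.873 for root and 0.908 for stem. Leaf was the most distinct organ, with correlations of 0.57 to 0.725 with root and stem libraries. Root and stem were closer in QYZM (r = 0.868) than in ZSZ1 (r = 0.751), and the QYZM root library was nearly as close to QYZM stem as to ZSZ1 root. These correlations are across genes, which are not independent replicates, and carry no test.

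**Figure D1:**
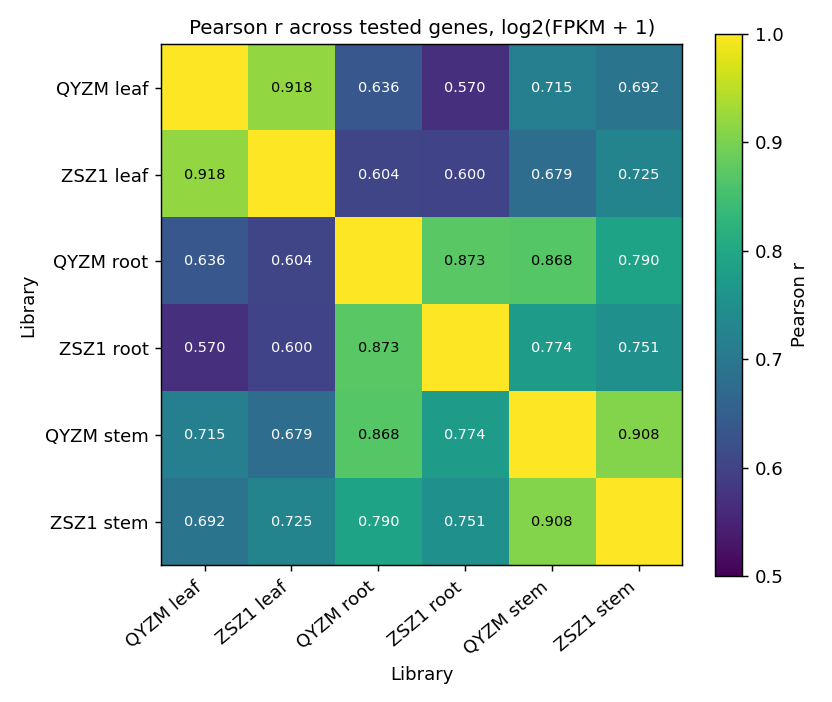
Pearson correlation of log2(FPKM + 1) across 14941 genes for each pair of the 6 libraries (both axes: variety and tissue; colour and printed number: r). The same-tissue pairs lie at 0.873 to 0.918, and the leaf libraries correlate at 0.57 to 0.725 with root and stem.

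The first comparison asked which genes differ between tissues on average over both varieties. A call did not require the same difference in each variety. Leaf expression was set against root expression with a limma model that held tissue and variety terms, so that each difference was judged against the departure of single libraries from additivity. Leaf and root differed in 5252 of 14941 genes at an adjusted p below 0.05 and at least 2-fold, with 1657 higher and 3595 lower in leaf. The gene most raised in leaf was Bnt04G006845, which stood at 2655 FPKM in QYZM leaf and 2695 in ZSZ1 leaf but at 2.0 FPKM in QYZM root and was listed at 0 in ZSZ1 root (log2 difference 10.59 ± 0.46, SE; limma adjusted p = 0.000564). Bnt01G001161 followed with 2322 and 1312 FPKM in leaf against 5.75 FPKM in QYZM root and a listed 0 in ZSZ1 root (9.39 ± 0.61, SE; limma adjusted p = 0.000937). On the lower side, Bnt13G018372 was near 0 in leaf and reached 268 FPKM in QYZM root and 324 FPKM in ZSZ1 root (-8.19 ± 0.74, SE; limma adjusted p = 0.00197). Bnt11G017074 was at 277 and 418 FPKM in root and at 0.449 and 0.451 FPKM in leaf (-7.88 ± 0.30, SE; limma adjusted p = 0.000564). Log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes, and where a library is listed at 0 they depend on the added 1.

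The balance of higher and lower genes in leaf depended on the scale and on the fold threshold, since at least 4-fold as deposited gave 967 higher and 890 lower genes. Over all tested genes the median leaf minus root difference was -0.57 as deposited. Median-of-ratios scaling, which by construction brings the median difference between libraries near 0, left -0.05 and gave 2305 higher and 1328 lower genes. Of these, 1647 and 1328 were called in the same direction as deposited, and no gene was called in opposite directions. Quantile normalization gave 2039 higher and 2008 lower genes, and a total without the highest genes, an alternative added after seeing the data, gave 1959 and 2224. Without QYZM leaf or without ZSZ1 leaf, which left 1 residual and 2.4 prior degrees of freedom, limma called 0 genes in this and the 3 other comparisons. For leaf against root 6399 and 4785 genes then had an unadjusted p below 0.05, and the difference of Bnt04G006845 was 10.99 and 10.20 (limma adjusted p = 0.0553 and 0.0522). Without ZSZ1 root limma called 3335.

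Leaf and stem differed in 4397 genes, of which 1215 were higher and 3182 lower in leaf. Bnt04G006845 again led the genes higher in leaf, at 0.574 and 0.619 FPKM in stem (10.71 ± 0.46, SE; limma adjusted p = 0.00124). Bnt05G008072 was at 512 and 415 FPKM in leaf and was listed at 0 in both stems (8.85 ± 0.29, SE; limma adjusted p = 0.00124). Bnt07G011851 was listed at 0 in both leaf libraries, with 910 FPKM in QYZM stem and 522 FPKM in ZSZ1 stem (-9.43 ± 0.62, SE; limma adjusted p = 0.00249). Bnt01G001591 stood at 2.40 and 1.45 FPKM in leaf against 378 and 358 FPKM in stem (-7.00 ± 0.30, SE; limma adjusted p = 0.00124). Here too the median difference was -0.57, and median-of-ratios scaling, which by construction moved it near 0 (-0.03), gave 1811 higher and 1120 lower genes. Quantile normalization gave 1682 higher and 1499 lower, and a total without the highest genes 1494 and 1805. Limma called 2064 genes without QYZM stem, 1455 without ZSZ1 stem (719 higher, 736 lower), and 0 without QYZM leaf or without ZSZ1 leaf, with 5798 and 4141 at an unadjusted p below 0.05.

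Stem and root were the most alike pair of organs. They differed in 802 genes, 544 higher and 258 lower in stem, and the median difference was 0.01. The genes with the largest rise in stem were Bnt13G018355, with 433 and 1009 FPKM in stem against 31.4 and 0.201 FPKM in root (6.73 ± 1.33, SE; limma adjusted p = 0.0495), and Bnt02G002335, with 4742 and 6513 FPKM in stem against 220 and 12.5 FPKM in root (6.67 ± 1.13, SE; limma adjusted p = 0.0353). In both, the QYZM root value was far above the ZSZ1 root value, and both calls were lost under median-of-ratios scaling, where both differences were 6.65 (limma adjusted p = 0.0782 and 0.0615), and without ZSZ1 stem, where they were 4.87 and 5.51 (limma adjusted p = 0.12 and 0.0844). Bnt11G017074 led the genes higher in root, at 0.451 and 0.762 FPKM in stem (-7.74 ± 0.30, SE; limma adjusted p = 0.00543). Bnt06G009762 was at 337 and 261 FPKM in root against 3.52 and 1.04 FPKM in stem (-6.62 ± 0.30, SE; limma adjusted p = 0.00668). The 14 genes with at least 50 FPKM in both stems that were chosen for at most 1% of the stem value in ZSZ1 root stood at a median of 10.45% of the stem value in QYZM root, and the same choice made in QYZM gave 1 gene, at 59.9% in ZSZ1 root. The number of genes called was 1801 without QYZM root, 494 without ZSZ1 root, 152 without ZSZ1 stem (67 higher, 85 lower) and 99 with no filter on low values (45 higher, 54 lower). Without QYZM leaf or without ZSZ1 leaf limma called 0, with 3114 and 3108 at an unadjusted p below 0.05. Both fits use the same root and stem libraries for this comparison, with the same differences, and are not separate checks.

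**Figure D2:**
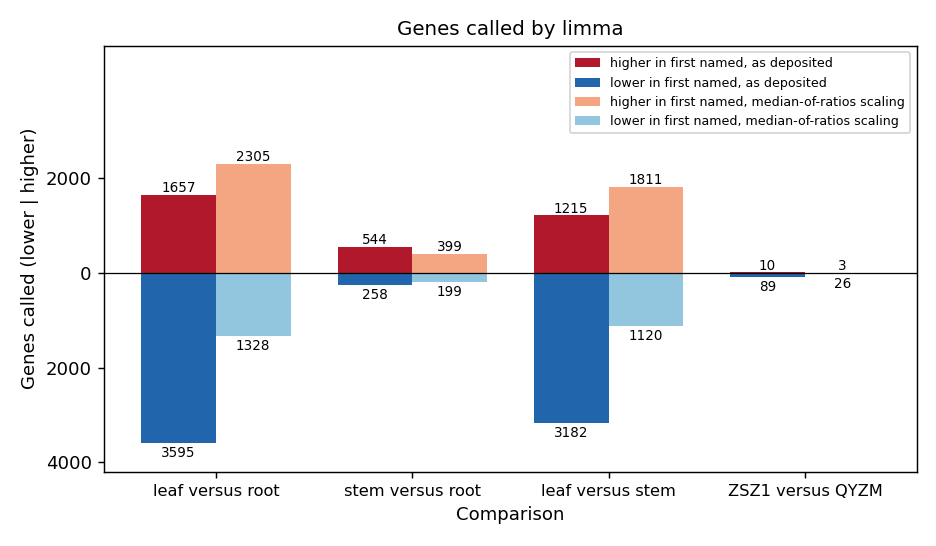
Number of genes called by limma in each comparison (bars above 0: higher in the first-named tissue or variety; bars below 0: lower), for values as deposited and after median-of-ratios scaling. For leaf against root the counts change from 1657 higher and 3595 lower to 2305 higher and 1328 lower.

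Tissue differences were then compared between the varieties, which share no library. The leaf minus root differences of single genes correlated at r = 0.806 between QYZM and ZSZ1 (Spearman 0.714), and the leaf minus stem differences at r = 0.81 (0.771). The stem minus root differences correlated less, at r = 0.596 (0.562). Of the genes at least 2-fold apart in both varieties, 4323 of 4432 had the same direction for leaf against root, 3956 of 4019 for leaf against stem and 1701 of 1875 for stem against root. The stem minus root differences had a standard deviation across genes of 0.90 in QYZM and 1.30 in ZSZ1. These are descriptions across genes, with no test.

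**Figure D3:**
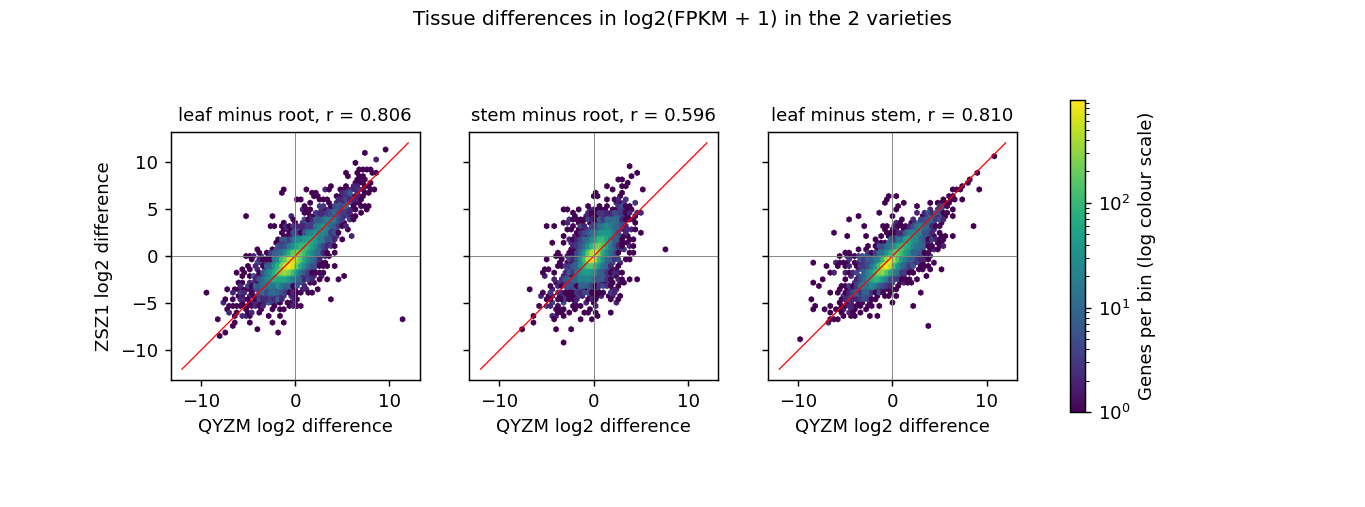
Difference in log2(FPKM + 1) between 2 tissues in QYZM (horizontal axis) and in ZSZ1 (vertical axis) for 14941 genes, with colour for the number of genes per bin on a log scale and a red line of equality. The correlation is 0.806 for leaf minus root, 0.596 for stem minus root and 0.81 for leaf minus stem.

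Genes enriched in one organ were counted in each variety by a rule of size, since single libraries allow no test: at least 1 FPKM in the tissue and FPKM + 1 at least 4 times that of both other tissues. Leaf had 758 such genes in QYZM and 528 in ZSZ1, of which 413 were shared, where independent lists would share 25.2. Root had 188 and 471 with 109 shared (5.6 if independent), and stem had 145 and 458 with 86 shared (4.2 if independent). The QYZM root library, which enters the QYZM root and stem counts, held the 14 stem genes described above at a median of 10.45% of their stem value. The shared leaf-enriched genes had a median of 67.3 FPKM in QYZM leaf and 62.5 FPKM in ZSZ1 leaf, against 1.37 to 5.43 FPKM elsewhere, and held 23.2% and 28.6% of the summed FPKM of these leaf libraries. The shared root-enriched genes held 2.6% of the total in QYZM root and 4.0% in ZSZ1 root, and the shared stem-enriched genes 3.0% and 3.8% of the stem totals. Under median-of-ratios scaling the shared leaf-enriched genes numbered 715. Genes at 1 FPKM or more in 1 tissue of both varieties and below it in every other library numbered 194 for leaf, 217 for root and 150 for stem.

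The last comparison set the cultivar against the wild accession. Over the 3 matched tissues, 99 genes differed between ZSZ1 and QYZM, 10 higher and 89 lower in ZSZ1. Whatever else the 3 libraries of a variety share, such as plants or handling, enters this difference and not the error term. The p-values cannot tell it apart from variety. Bnt01G000084 was listed at 0 in all 3 QYZM libraries and stood at 41.7 FPKM in leaf, 41.3 FPKM in root and 35.4 FPKM in stem of ZSZ1 (5.33 ± 0.23, SE; limma adjusted p = 0.00542). Bnt01G000006 was likewise listed at 0 in QYZM, with 8.95, 15.9 and 12.7 FPKM in leaf, root and stem of ZSZ1 (3.72 ± 0.27, SE; limma adjusted p = 0.0172). Bnt01G000085, whose identifier directly follows the first of these, stood at 796, 150 and 300 FPKM in leaf, root and stem of QYZM, against 0.28 FPKM in ZSZ1 leaf and listed values of 0 in ZSZ1 root and stem (-8.25 ± 0.40, SE; limma adjusted p = 0.00542). Bnt11G016608 stood at 95.2, 189 and 112 FPKM in QYZM leaf, root and stem and at no more than 1.56 FPKM in ZSZ1 (-6.22 ± 0.24, SE; limma adjusted p = 0.00542). The median difference over all tested genes was -0.20 as deposited and, by construction, near 0 (0.01) after median-of-ratios scaling, which left 29 genes called (3 higher, 26 lower). With no filter on low values limma called 0, with 2443 of 18604 at an unadjusted p below 0.05. With a mean of at least 5 FPKM, Bnt01G000006 lost its call at an unchanged difference of 3.72 (limma adjusted p = 0.0588). Limma called 287 without QYZM root (48 higher, 239 lower), 276 without ZSZ1 root (49 higher, 227 lower) and 0 without QYZM leaf or without ZSZ1 leaf. The latter had 1393 and 1396 of 14941 genes at an unadjusted p below 0.05, which a share of 0.05 would pass with no difference. Leaving out a library takes its whole tissue out of this comparison. The fits without either root library are therefore not separate checks, nor are those without either leaf library.

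**Figure D4:**
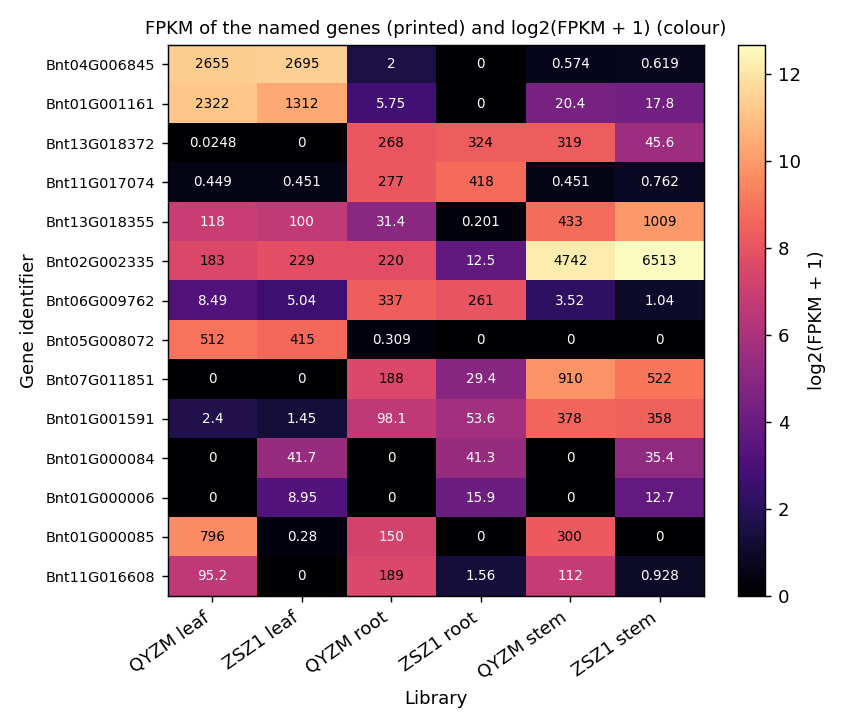
FPKM of the named genes (rows, by identifier) in the 6 libraries (columns), printed in each cell, with colour for log2(FPKM + 1). Bnt01G000084 is listed at 0 in all 3 QYZM libraries and lies between 35.4 and 41.7 in ZSZ1, while Bnt01G000085 lies between 150 and 796 in QYZM and between 0 and 0.28 in ZSZ1.

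Within single tissues, genes at least 4-fold apart between the varieties were 3.6% of those compared in leaf (105 higher and 393 lower in ZSZ1), 4.8% in root (252 higher and 455 lower) and 3.3% in stem (151 higher and 323 lower). With 1 library against 1 these counts have no replicate check and no test. The median ZSZ1 minus QYZM difference was -0.41 in leaf, -0.13 in root and -0.06 in stem, and after median-of-ratios scaling the leaf counts were 198 higher and 302 lower. A gene at least 4-fold apart in all 3 tissues was higher in ZSZ1 in 7 cases and lower in 60.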

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

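A total of 21 genes were enriched in one tissue in QYZM and in another tissue in ZSZ1 by the 4-fold rule, where lists drawn independently would give 65.1. Of these, 14 were enriched in stem in QYZM and in root in ZSZ1, against 4.3 for independent lists of 145 and 471 genes. They were picked out because the difference between tissues ran in opposite directions in the 2 varieties. That difference was not tested, since each tissue of each variety had 1 library, and which genes take part was not examined further.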

How the results depend on the processing

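The total without the highest genes, and following the percent of called genes that were higher, were chosen after the results were seen. Each named gene's difference kept its direction under all 19 alternatives. The naming rule, which took the largest differences with the same sign in every variety or tissue, largely fixed this outcome. Each call was lost with either leaf library left out. The stem-higher Bnt13G018355 (log2 difference 4.11 to 9.35) and Bnt02G002335 (4.46 to 8.88) lost their calls under 12 and 8 alternatives. The named variety genes also lost theirs with no filter on low values, at unchanged differences (limma adjusted p = 0.051 to 0.0699). Bnt01G000006 (1.79 to 6.94) lost its call with a mean of at least 5 FPKM too, at an unchanged 3.72. The other genes named for the tissue comparisons lost theirs under no further alternative, with ranges such as 8.82 to 12.51 for Bnt04G006845 and -9.27 to -5.99 for Bnt11G017074 in leaf against root. The number of genes called moved more than 1.5 times from the reported count as follows, and the cause was not tested except where the alternative itself removes genes or libraries. A pseudocount of 5 gave 3208 genes for leaf against root, 2787 for leaf against stem and 31 for ZSZ1 against QYZM. No filter gave 99 for stem against root and 0 for ZSZ1 against QYZM (2443 at an unadjusted p below 0.05), and a mean of at least 5 FPKM gave 27 for the latter. A total of 1000000 per library gave 417 (stem against root) and 39 (varieties). Median-of-ratios scaling gave 2931 for leaf against stem and 29 for the varieties, quantile normalization 23 and the total without the highest genes 30 for the varieties. A fold threshold of 4 gave 1857 for leaf against root and 1536 for leaf against stem. Without the blocking term, stem against root had 486 and the varieties 18. Leaving out 1 library gave 0 to 4853 genes for leaf against root, 0 to 1801 for stem against root, 0 to 5337 for leaf against stem and 0 to 287 for the varieties. The 0 arose in all 4 comparisons when a leaf library was missing, which leaves 1 residual degree of freedom from the root and stem libraries and 2.4 prior degrees of freedom, against 6.6 to 6.72 without another library. The remaining library of the tissue is then assumed to vary like the others. That library is fitted exactly, so it adds nothing to the variety comparison or to the error term.

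The percent of called genes that were higher was 31.5 for leaf against root and turned to 63.4 under median-of-ratios scaling, 50.4 under quantile normalization and 52.1 at a fold threshold of 4, with 46.8 without the highest genes in the total. For leaf against stem it was 27.6, with 61.8, 52.9, 41.9 and 45.3 under the same settings and 28.3 to 49.4 with 1 library left out. For stem against root it was 67.8, with 45.5 with no filter and 44.1 to 70.8 with 1 library left out. For the varieties it was 10.1, with 20.2 at a pseudocount of 0.1, 3.7 at a mean of at least 5 FPKM and 13.1 to 17.8 with 1 library left out. Of the counts of detected genes at minimums of 0.1 and 5 FPKM, only ZSZ1 leaf at 5 FPKM (7883) moved more than 1.5 times. Shared tissue-enriched genes numbered 987, 372 and 520 (leaf, root, stem) at a 2-fold rule and 177, 36 and 19 at an 8-fold rule. They numbered 715 for leaf under median-of-ratios scaling, and 207 for root and 161 for stem at a pseudocount of 0.1. Genes apart between varieties in leaf, root and stem numbered 2715, 3087 and 1897 at a 2-fold rule, 148, 223 and 155 at an 8-fold rule, and 1168, 1545 and 1046 at a pseudocount of 0.1. In leaf, 39.6% of them were higher in ZSZ1 after median-of-ratios scaling, against 21.1% as deposited. Correlations of tissue differences between varieties stayed within 0.05 of the reported values under all 5 alternatives. Leaving out a library could not be applied to rules that use 1 library per tissue and variety. The gene list tests were not run, because the identifiers have no names. Without read counts, low values have no counting error, and the pseudocount sets the weight they carry.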

Other observations

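The counts of consecutive genes and of genes seen in 1 variety, and the tests of library totals, of abundant genes as the whole cause, of scaling between varieties (called genes and genes apart within a tissue) and of how well ZSZ1 reads match the gene models, were chosen after the results were seen. Some genes enriched in the same tissue in both varieties had consecutive identifiers, more of them than random placement gave in root and leaf. The 109 shared root-enriched genes formed 10 consecutive pairs (18 genes), against a mean of 0.6 in 2000 random placements (permutation p = 0.0005, the smallest these can give). The 413 leaf-enriched genes formed 21 pairs (41 genes) against 8.5 (permutation p = 0.0005), while the 2 pairs of the 86 stem-enriched genes, against 0.4, did not pass (permutation p = 0.0585). What these genes encode is not known here.

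Genes listed at 0 in all 3 libraries of one variety and at 1 FPKM or more in all 3 of the other numbered 32 seen in QYZM and 17 seen in ZSZ1, and the 3 other splits with 1 library per tissue on each side gave 0 such genes in either direction. Of the 67 genes at least 4-fold apart between varieties in all 3 tissues, 2 pairs had consecutive identifiers and opposite directions. One pair is Bnt01G000084 and Bnt01G000085, which prompted the count, so no test of it is given. The other, named after its values were seen, is Bnt12G017418, at 4.36 to 6.20 FPKM in QYZM and listed at 0 in ZSZ1, and Bnt12G017419, listed at 0 in QYZM and at 3.31 to 3.80 FPKM in ZSZ1. The summed FPKM of the first pair was 19.0, 3.64 and 8.48 times as high in QYZM as in ZSZ1 in leaf, root and stem, and that of the second pair 1.63, 1.32 and 1.25 times as high.

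In QYZM, genes high in stem were seldom near 0 in root: 2 genes with at least 50 FPKM in stem had at most 1% of that in root, against 21 in ZSZ1. Of 14 stem genes chosen in ZSZ1, 0.0% lay under 25% of their median share in QYZM root (95% bootstrap interval 0.0 to 14.3), and of 44 genes in a wider set, with a median of 10.65%, 2 did (4.5%), both under the bound of 10% set beforehand for mixed-in stem. A mixed-in portion with the make-up of the stem sample gives every stem gene at least its share, however, and the lowest shares were 2.77% among the 14 and 0.72% among the 44, far under the medians of 10.45% and 10.65% (1 stem gene chosen the same way in QYZM stood at 0.0% in QYZM root and 59.9% in ZSZ1 root). Carry-over from every QYZM library is argued against by 95 leaf genes, whose median share in QYZM root was 0.095 times that of the stem genes (0.067 to 0.186), while root material in the QYZM stem sample stays open: the ratio of median shares was 0.633, past the bound set beforehand, but its interval of 0.047 to 4.874 over 8 genes spans both bounds, and conditions on this interval and on the lowest share were added after they were seen. A smaller portion of stem, or stem tissue of another make-up, stays open, as does expression of stem genes in QYZM roots, which was not tested.

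Most genes had lower values in leaf, with a median leaf minus root difference of -0.57 (-0.38 in QYZM and -0.72 in ZSZ1), and the bootstrap intervals given here resample genes only, not libraries. Library totals are argued against by a median of -0.54 (95% bootstrap interval -0.55 to -0.52; -0.52 in QYZM and -0.53 in ZSZ1) with every library at the mean total, while the -0.61 at totals of 1000000 decides nothing, since those totals also raise every value against the added 1. The shift was not confined to low genes, where low depth would place it. Among 7432 genes with a mean of at least 10 FPKM the median was -0.69 (-0.71 to -0.67, with -0.43 in QYZM and -0.91 in ZSZ1). That mean covers the root and stem libraries too, which favours genes low in leaf, so the size of this median is not read further. If whole fragments were counted, estimated relative depth was 0.95 in QYZM leaf and 0.91 in ZSZ1 leaf, against 0.91 and 1.06 in root. Leaving 287 of the highest genes out of the total moved the median to -0.3 (-0.32 to -0.28, with -0.28 in each variety). These 287 genes may thus account for part of the shift and are argued against as its whole cause. Whether they account for most of it is undecided. The interval spans the bound set beforehand at the midpoint between the shift and 0, which was -0.29. Abundant genes below this cut-off stayed in the total, so a longer list of them stays open. A difference between leaf and root tissue also stays open, untested.

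More genes were lower than higher in ZSZ1. Of the called genes, 10.1% of 99 were higher as deposited and 10.3% of 29 after median-of-ratios scaling (exact 95% interval 2.2 to 27.4). This argues against scaling as the whole source of their imbalance, since the interval lies below an even split. Its upper end passes the bound set for a firm verdict, however. All 29 were among the 99, and the interval takes genes as independent. For genes at least 4-fold apart within a tissue scaling stays open. There the percent higher moved from 21.1 to 39.6 in leaf, from 35.6 to 41.3 in root and from 31.9 to 36.4 in stem. Poorer matching of ZSZ1 reads to the gene models may contribute: 65.3% of the 49 genes seen in 1 variety were seen in QYZM (exact 95% interval 50.4 to 78.3, exact two-sided binomial p = 0.044). Minimums of 2 and 5 FPKM gave exact binomial p = 0.12 and p = 0.092, and these tests take genes as independent. The minimums were applied as deposited, where ZSZ1 values ran lower (median difference -0.41 in leaf), so scaling can also tilt this count. Poorer matching stays open, as does a difference between the varieties themselves. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) called as many as 99 genes, and the highest other called 0. Only 3 of the others had 1 library per tissue on each side, and these put a consistent variety difference largely into the error term. The rest overlap with the tissue term, so the 0 calls decide nothing. With 10 splits the share cannot fall under 0.05.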
